A study of Cricetulus griseus with 19 samples.

How the data were processed

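Polyadenylated RNA was sequenced from 19 libraries of Paradaux cells, a derivative of CHO-K1, which is an ovary-derived cell line of the Chinese hamster. Per the labels, 1 library came from the parental line, 4 from long-term cultures with uncontrolled growth, 7 from cultures under negative feedback and 7 from cultures under paradoxical feedback. Per the labels' protocols, cells were harvested after 2 days of growth kept below 80% confluence, RNA was isolated with a Qiagen kit, and libraries were built with the NEBNext Ultra II kit. Each library was taken as a separate culture by its label. The labels do not say whether the numbered cultures were propagated separately throughout, so the p-values measure the spread between these samples, part of which may be technical.

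The submitters' processing notes name Trim Galore and kallisto without versions. The genome build and the annotation behind the index are not given in the sources used here. The deposited files hold, per the file headers, 1 row for each of 46718 transcript targets with its length, its effective length, an estimated count and a TPM value. The estimated count deposited by the authors is the number of reads that kallisto assigned to a target, and it need not be whole because a read that matches several targets is shared among them. The deposited TPM values scale the estimated counts by effective length to a common total. The effective lengths were the same in all 19 files, so a rescaling of TPM by length gave the same values and was not run as an alternative. TPM was used only to describe the inserted construct.

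The targets carry RefSeq accessions and no symbols. A table of genes of assembly CriGri-PICRH-1.0 was used for names only, since the files' build is unknown, and no coordinates are printed. It matched 528 targets by accession, of which 334 were protein coding under 330 symbols. These are called named genes. The predicted transcripts, which make up most targets, matched no symbol, so estimated counts could not be summed to genes as the planned design had assumed. Every test was therefore made per transcript target. A target was called whole where its estimated count was a whole number, within 1e-06, in all 19 libraries. For other targets the division of reads among similar transcripts adds an uncertainty that the files do not show, and named genes of this kind are marked as having shared reads.

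Estimated counts were rounded to whole numbers. Library totals ran from 9.91 to 13.2 M estimated counts, with a mean of 11.7 M. Floors for targets at 0 were set at 3 counts per library and cover counting error only, because reads without molecular identifiers are not independent molecules. Counts were filtered with filterByExpr, which left 28555 targets, 284 of them named and 5933 whole. They were normalized by TMM and fitted with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with 1 coefficient per group and all 19 libraries in a single fit. P-values were adjusted by the Benjamini-Hochberg method over all tested targets, and a target was called at an adjusted p under 0.05. All adjusted p-values for genes come from this test unless another is named. CPM values use the TMM-scaled library sizes. The 4 comparisons were negative feedback against uncontrolled, paradoxical feedback against uncontrolled, paradoxical against negative feedback, and the mean of the 3 long-term groups against the parental line. The parental line has 1 library, so the last test assumes that it would vary like the cultures.

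Of 42 gene lists fixed before the data were examined, 11 had at least 4 tested members. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and the p-values were adjusted over the lists of each comparison. Camera with an estimated correlation and the rotation test fry were alternatives. Because few fixed members had names, 18 further lists were assembled from the names that matched, after the files had been seen and before any comparison was made, and 16 of them had at least 4 tested members. The genes named in the text follow a rule fixed beforehand. It takes up to 8 symbols with the highest and 8 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 1, up to 3 called members of each list, and a set of genes fixed by function. It also takes any target that is not a hamster transcript. Exceptions are marked as chosen after their values were seen. Some genes that the rule takes are not reported here. Of 18 genes fixed by function, 6 were matched and tested.

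The spread between cultures of a group was the root-mean-square log2 CPM difference over all tested targets, averaged over pairs. Groups were compared by exact two-sided permutation of each culture's mean squared distance to its group mean, multiplied by n/(n-1). The relation between both feedback comparisons used differences of mean log2 CPM, with 1000 simulated draws of unchanged groups against the same 4 control libraries and with those controls split into pairs. A length index was computed per library as the log2 level of targets over 3000 nt relative to those under 1200 nt, after centring each target, and the share of counts on targets under 800 nt was computed as well.

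The test was checked on simulated counts for 28555 targets in the comparison of negative feedback with uncontrolled cultures. At the fitted spread it recovered 12% of 50 targets changed 2-fold, 36% of those changed 4-fold, 58% of those changed 8-fold and 52% of those changed 16-fold, with 7 false calls among 86. Counts were simulated independently for each target, without differences between libraries that many targets share. The shares recovered and the false calls therefore need not hold for the real calls. The spread and relation calculations recovered the values used to simulate 20000 genes to within 0.498%.

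Alternatives fixed beforehand were RLE and plain library-size scaling, no count filter, a filter of CPM of at least 1 in at least 4 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, and leaving out each culture. After the data had been seen, further alternatives were added. These were whole targets only, the length index as a covariate, removal of a smooth trend with target length from each library, list tests against named genes alone, edgeR's fitted fold changes in the relation, and omission of negative feedback cultures 3 to 7, which no label sets apart. They were noticed because they lay together on the first principal component, and their low share of counts on short targets was seen after that, so this fit is a check of how far the results rest on them and not a test of a group. No pair of libraries of the same group agreed within sampling noise, and no library was left out of the tests. The closest pair, negative feedback cultures 4 and 6, had a chi-square per degree of freedom of 1.81 over whole targets. Pairs of uncontrolled cultures had 18.0 to 33.2.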

Results

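RNA was measured in 19 libraries of Paradaux, a derivative of the CHO-K1 hamster cell line that carries a synthetic circuit for the control of cell number. Under negative feedback a signal made by the cells limits their own population, whereas under paradoxical feedback the same signal acts on both growth and death. The series sampled 4 long-term cultures that grew without control, 7 kept under negative feedback, 7 kept under paradoxical feedback, and 1 library of the parental line. The labels give these as culture conditions, and the same inserted construct was detected in every library. Library totals were 11.3 ± 0.853 M estimated counts in the uncontrolled group (SD, n = 4), 11.7 ± 1.15 M under negative feedback (SD, n = 7) and 12.0 ± 0.459 M under paradoxical feedback (SD, n = 7), with 11.5 M in the parental library. Log2 fold changes are given with the standard error of the fit, and levels in CPM are given as mean ± SD over cultures. Genes with shared reads, meaning reads that the quantifier divided among similar transcripts, carry an extra uncertainty and are marked as such.

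The cultures under negative feedback fell into separate sets on the first principal component, which held 33.2% of the variance over all tested targets. Negative feedback cultures 1 and 2 lay at -161 and -141, within the range of the uncontrolled cultures (-169 to -122), and cultures 3 to 7 lay at 158 to 221. The paradoxical feedback cultures lay between, at -79.7 to 38, and the parental library at -84.2. The same libraries differed in the share of counts on short transcripts. Targets under 800 nt took 12.2 to 13.4% of the counts in uncontrolled cultures, 14.1 and 13.3% in negative feedback cultures 1 and 2, 6.12 to 7.22% in cultures 3 to 7, and 8.50 to 12.4% under paradoxical feedback, against 11.8% in the parental library. By exact two-sided permutation, this share differed between paradoxical feedback and uncontrolled cultures with p = 0.0121, which became 0.0727 after Benjamini-Hochberg adjustment over 12 library comparisons. For negative feedback against uncontrolled cultures the exact p was 0.0545 (adjusted 0.109). Of the 12 comparisons 1 passed. The median log2 level of named targets whose length is a multiple of 3, as in records of coding sequence alone, was 0.63 higher under paradoxical feedback than in uncontrolled cultures (exact p = 0.00303, adjusted 0.0364). Such a length also occurs by chance, and 37.9% of predicted coding transcripts had it, so the set may also hold targets with untranslated ends.

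**Figure D1:**
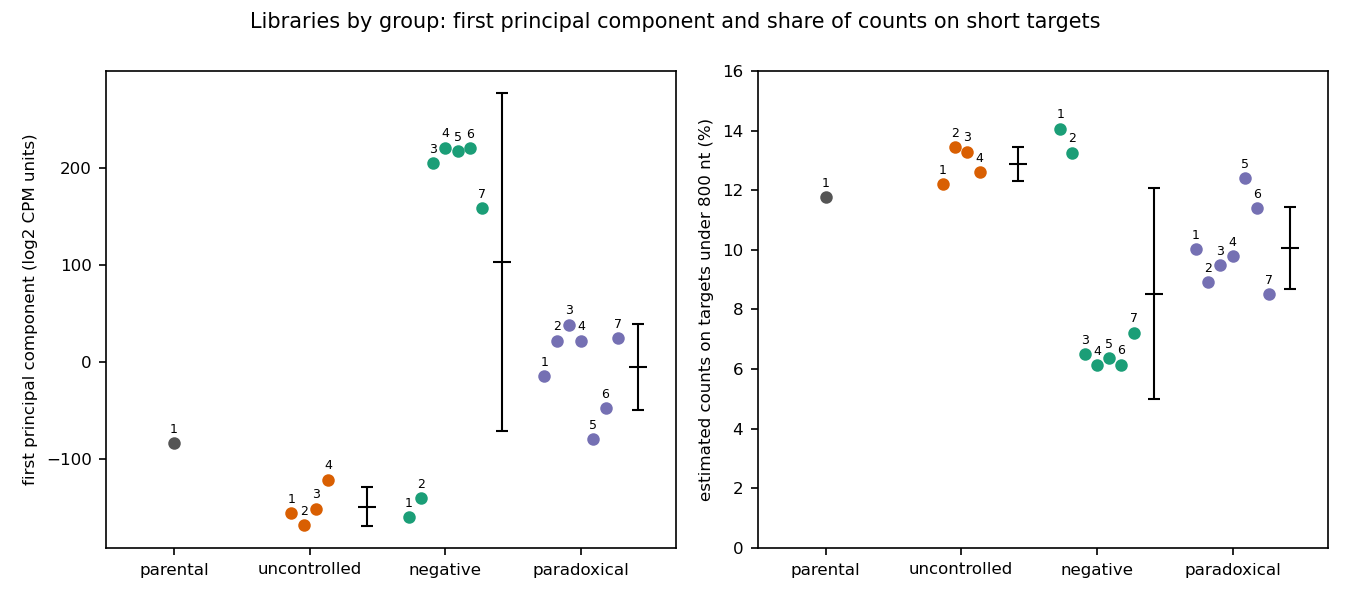
Score of each library on the first principal component of log2 CPM (left) and percentage of its estimated counts on targets under 800 nt (right), by group, with points numbered by culture and bars showing mean and SD. Negative feedback cultures 3 to 7 stand apart from cultures 1 and 2 on both axes, at 6.12 to 7.22% against 14.1 and 13.3% of counts on short targets.

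The inserted construct was detected in every library, and no difference between groups passed the test. The index held 1 target that is not a hamster transcript, an insert of 8694 nt named vYM133_linearized_insertion in the files, and its position in the genome was not analysed here. It reached 1703 CPM in the parental library, 1942 ± 263 CPM in uncontrolled cultures (SD, n = 4), 1789 ± 269 CPM under negative feedback (SD, n = 7) and 1751 ± 405 CPM under paradoxical feedback (SD, n = 7). Its adjusted p by edgeR was 0.652 for negative feedback against uncontrolled, 0.630 for paradoxical feedback against uncontrolled and 0.962 between both feedback conditions. The log2 fold changes were -0.12 ± 0.17, -0.15 ± 0.17 and -0.03 ± 0.14. In TPM the insert was at 218 in the parental library and at 219 to 266 in uncontrolled cultures. It was at 242 to 307 TPM under negative and 177 to 262 TPM under paradoxical feedback. By this unit the lowest and highest values under negative feedback were above those of uncontrolled cultures, whereas in CPM the mean was below. TPM was not tested. Because the insert is a single target, its levels do not separate the parts of the circuit.

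Comparison of negative feedback with uncontrolled growth asked how cultures kept under growth-limiting feedback differed from free-growing ones. Among genes with whole counts, Cdk2, Cdc25b and Top2a were called higher under negative feedback, while the G1/S list did not pass camera (adjusted p = 0.139). Cdk2, a kinase of the G1/S transition, stood at 42.6 ± 24.3 CPM (SD, n = 7) against 7.5 ± 1.32 CPM (SD, n = 4), a log2 fold change of 2.50 ± 0.54 (edgeR adjusted p = 0.0236). Cdc25b, a phosphatase that activates mitotic kinases, rose by 2.12 ± 0.43, and Top2a, the topoisomerase of dividing cells, by 1.48 ± 0.37. These means joined cultures that differed widely. Cdk2 was at 6.61 and 8.18 CPM in cultures 1 and 2 and at 51.9 to 61 CPM in cultures 3 to 7, and Top2a was at 343 and 297 CPM in the former and 951 to 1399 CPM in the latter. Cultures 3 to 7 were also those with 6.12 to 7.22% of counts on short targets.

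By fixed list, called genes under negative feedback rose, many of them mainly in cultures 3 to 7. Casp2 was at 12.9 to 19.7 CPM there against 0.446 and 0.779 CPM in cultures 1 and 2, and Edem1 at 24.3 to 49.2 CPM against 1.79 and 1.65 CPM. Without cultures 3 to 7 the log2 fold changes of Casp2, Edem1, Cdt1, Slc2a1, Srebf2 and Acaca were below 0, at -0.51, -0.20, -0.21, -0.058, -0.14 and -0.015. Those of the other called genes in this paragraph ran from 0 for Ldha to 0.35 for Icam1. No named gene was called in that fit, which leaves 2 negative feedback cultures. Of 5 tested apoptosis genes, Casp2 and Casp8, an initiator caspase, rose by 3.72 ± 0.92 and 0.69 ± 0.19, and the other members were not called. Of 4 heat shock chaperones, Hsph1 (1.37 ± 0.32) and Hsp90aa1 (1.20 ± 0.30) rose. Of 9 members of the unfolded protein response, Edem1, which directs misfolded glycoproteins to degradation, rose by 3.85 ± 0.84 and Hyou1, with shared reads, by 1.00 ± 0.28. Glycolysis had 3 of 5 members called, namely the glucose transporter Slc2a1 (1.25 ± 0.34), Pgk1 (0.56 ± 0.17) and Ldha, with shared reads. The Ldha target was at 0 in every uncontrolled culture and at least 5.37-fold higher against a floor of 3 counts per library (3.38-fold without negative feedback culture 4). This does not give the level of the gene, because counts were not summed over similar transcripts. The lysosomal genes Lamp2 (1.31 ± 0.35) and Npc1 (0.75 ± 0.20) were called among 4. Parp1, a DNA repair enzyme, rose by 1.31 ± 0.28 among 6 repair genes, and Cdt1, a replication licensing factor, by 1.68 ± 0.49 among 6 G1/S genes. Single called members of smaller lists were Acaca, the first enzyme of fatty acid synthesis (1.85 ± 0.45), Srebf2, a regulator of sterol synthesis (1.14 ± 0.31), the adhesion molecule Icam1 (1.37 ± 0.37) and the elongation factor Eef2 (0.38 ± 0.11). Named genes as a whole had a median log2 fold change of 0.44, so the rises of Eef2 and Pgk1 are near that of a typical named gene. None of 9 ribosomal proteins, 4 epigenetic silencing genes, 4 NRF2 targets or 4 drug efflux and detoxification genes was called. Adjusted over the list alone, 5 of the 6 G1/S genes and all 4 chaperones passed as higher, and 1 apoptosis gene, 1 repair gene and 1 NRF2 target passed as lower. Adjusted p-values of these called genes ran from 0.0236 to 0.0497 by edgeR.

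The highest called symbols were single transcript targets near the detection limit in uncontrolled cultures, all with shared reads. Counts were not summed to genes, so a target near 0 does not show that its gene was near 0. Slc35a3, a Golgi sugar-nucleotide transporter, was at 0 in every uncontrolled culture and at least 28.9-fold higher under negative feedback. Dicer1, the microRNA processing enzyme, was at 0.288 ± 0.342 CPM (SD, n = 4) against 41.8 ± 29.8 CPM (SD, n = 7). Both rises lay in negative feedback cultures 3 to 7, since Slc35a3 was at 0 and Dicer1 at 0 and 0.195 CPM in cultures 1 and 2, against 4.94 to 15.4 CPM and 49.4 to 74.6 CPM in the others. Gbf1, Smu1, Gnaq, Mgat1, Mbtps2 and Ccnd1 followed, at log2 fold changes from 4.53 to 5.92. Without cultures 3 to 7 the log2 fold change was 0 for Slc35a3, -1.49 for Dicer1, -0.70 for Smu1, -0.50 for Gnaq and -0.16 for Ccnd1. Slc20a1, a phosphate transporter with shared reads, was the only named gene called lower by edgeR over all targets, by 0.55 ± 0.15 on the log2 scale, and 14 were lower when adjusted over named genes alone. Of the genes fixed by function, Ahr (1.97 ± 0.67, shared reads), Xiap (2.62 ± 0.97), Casp9 (-0.88 ± 0.45, shared reads), Abcb1 (-0.01 ± 0.16, shared reads) and Abcb1b (-1.44 ± 1.48, shared reads) did not pass, with adjusted p of 0.0684, 0.0881, 0.184, 0.964 and 0.519 by edgeR.

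Over all 28555 targets, edgeR called 2787 at an adjusted p under 0.05, 2470 higher and 317 lower under negative feedback, and 8904 had an unadjusted p under 0.05. Among 284 named genes, 80 were higher and 1 lower, with 44 and 24 by limma-voom. No fixed list passed camera (0 of 11, smallest adjusted p = 0.0824, or 0.784 with an estimated correlation), while 3 had an unadjusted p under 0.05 and fry called 2. Leaving out uncontrolled culture 1, 2, 3 or 4 left 14, 7, 7 or 15 calls, leaving out negative feedback culture 1 or 2 gave 6931 or 6329, and leaving out culture 3, 4, 5, 6 or 7 gave 1230, 954, 1048, 1167 or 1468. With cultures 3 to 7 left out together 13 targets were called, and limma-voom called 5039 targets with 1637 higher and 3402 lower. Few calls also remained in the fit of only the groups compared and with the length index as a covariate.

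Comparison of paradoxical feedback with uncontrolled growth asked the same of the condition in which the signal acts on both growth and death. Cytosolic chaperones rose together, while the main chaperone of the endoplasmic reticulum fell. Hspa8, the constitutive member of the Hsp70 family, stood at 3767 ± 920 CPM (SD, n = 7) against 1200 ± 456 CPM in uncontrolled cultures (SD, n = 4), a log2 fold change of 1.65 ± 0.33 (edgeR adjusted p = 0.0144). Hspa5, the Hsp70 protein of the endoplasmic reticulum also called BiP, stood at 1993 ± 632 CPM against 7902 ± 3286 CPM, a log2 fold change of -1.99 ± 0.56 (edgeR adjusted p = 0.0431). All 7 paradoxical feedback cultures (1071 to 2802 CPM) lay below all 4 uncontrolled cultures (4868 to 11184 CPM) for Hspa5, and the parental library lay in between, at 3718 CPM. The Hspa5 call was lost when any 1 of the uncontrolled cultures or of paradoxical feedback cultures 1, 2, 3, 5, 6 and 7 was left out, with log2 fold changes of -2.16 to -1.77 and adjusted p from 0.0614 to 0.127 by edgeR.

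Of 4 tested heat shock chaperones, all were called higher, with Hsph1 at 1.55 ± 0.32 and Stip1, which links Hsp70 to Hsp90, at 0.95 ± 0.19. The list passed camera (adjusted p = 0.000472), but not with an estimated correlation (adjusted p = 0.172). The G1/S list passed as well (adjusted p = 0.00292, and 0.172 with an estimated correlation), with 3 of 6 members called and 5 adjusted over the list alone. Its called members were Pcna, the sliding clamp of DNA polymerase (1.55 ± 0.33), the licensing factor Cdt1 (1.67 ± 0.49) and thymidine kinase Tk1 (1.64 ± 0.41, shared reads). Cdt1 was called in only 9 of 30 alternatives, Hspa5 in 18 of 30, Pcna in 27 of 30 and Tk1 in 23 of 29. Glycolysis passed at an adjusted p of 0.0466 (0.172 with an estimated correlation), with Pgk1 called (0.81 ± 0.18) among 5 members and 3 adjusted over the list alone. Of 9 members of the unfolded protein response, Hspa5 was the only one called, and Creld2, another of its targets, missed the threshold at -1.74 ± 0.51 (adjusted p = 0.0508 by edgeR). The list itself did not pass (adjusted p = 0.344), and 2 members passed as lower when adjusted over the list alone. Among 4 NRF2 targets, the peroxiredoxin Prdx1 rose by 1.09 ± 0.25 with shared reads. Rps4x, at 0.87 ± 0.15, was the only 1 called of 9 ribosomal proteins, whose median log2 fold change was -0.038. The elongation factors Eef2 and Eef1a1 rose by 0.62 ± 0.11 and 0.73 ± 0.15, the latter with shared reads. Parp1 rose by 1.25 ± 0.28 among 6 repair genes, Cbx3 by 0.70 ± 0.18 among 4 silencing genes, and Icam1 by 1.77 ± 0.38. Sdhc, a subunit of respiratory complex II with shared reads, rose by 0.59 ± 0.11. Named genes as a whole had a median log2 fold change of 0.55, against 0.02 for other targets. The rises of Sdhc and Eef2 are therefore near that of a typical named gene. No gene of the apoptosis, lysosome or drug efflux and detoxification lists was called among 5, 4 and 4. Against the other named genes alone, the heat shock list passed as higher (adjusted p = 0.0411), the unfolded protein response passed as lower (0.0236) and the G1/S list had 0.160, and with an estimated correlation the first 2 had 0.497 and 0.424. In the same libraries, targets under 800 nt took 10.1 ± 1.38% of the counts under paradoxical feedback (SD, n = 7) and 12.9 ± 0.579% in uncontrolled cultures (SD, n = 4).

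**Figure D2:**
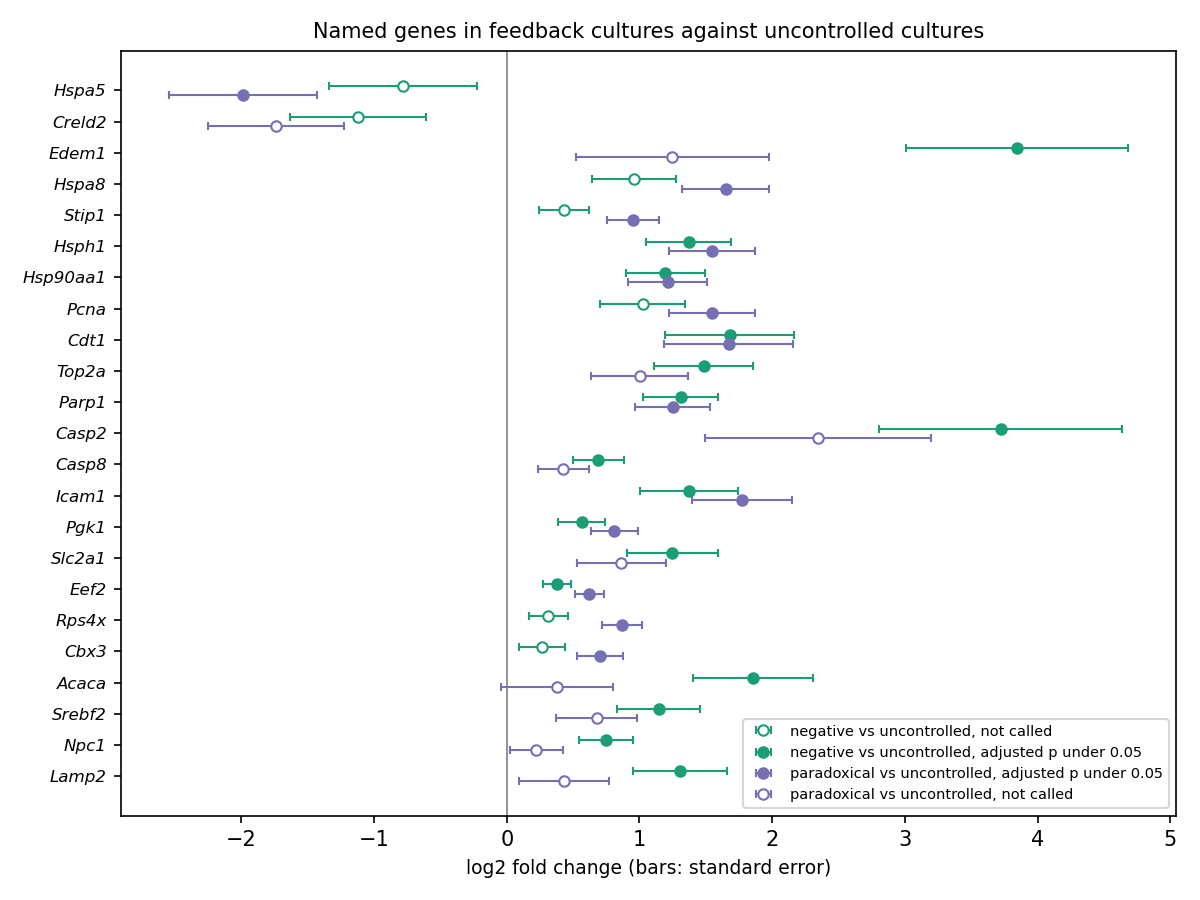
Log2 fold change of 23 named genes with whole counts in negative feedback (green) and paradoxical feedback (purple) cultures against uncontrolled cultures, with bars of 1 standard error and filled points for an adjusted p under 0.05 by edgeR. Hspa5 is the only filled point to the left of 0, at -1.99 under paradoxical feedback, and Hspa8 lies at 1.65.

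Among other named genes, Cdk2 (2.32 ± 0.53) and the antioxidant enzyme Gpx1 (2.26 ± 0.65) rose most among those with whole counts, and Cdc25b (1.93 ± 0.43) and Adk, adenosine kinase (0.98 ± 0.20), were also higher. Dicer1, Smu1, Mgat1, Gna11 and Apex1, all with shared reads, rose by 2.39 to 5.40. The call held in 11 of 30 alternatives for Gpx1 and in 24 of 30 for Cdk2. Of 29 alternatives it held in 9 for Dicer1, 10 for Smu1, 24 for Mgat1, 22 for Gna11 and 27 for Apex1. Besides Hspa5, the named genes called lower by edgeR over all targets were Slc20a1, by 0.82 ± 0.15 with shared reads, and Gmds, an enzyme of GDP-fucose synthesis, by 0.80 ± 0.21. Abcb1, Abcb1b, Ahr, Casp9 and Xiap did not pass, with adjusted p between 0.223 and 1 by edgeR. In all, edgeR called 1835 of 28555 targets, 1408 higher and 427 lower, and 7381 had an unadjusted p under 0.05. Among the 284 named genes, 56 were higher and 3 lower, with 89 and 8 when adjusted over named genes alone. Scaling by library size alone gave 905 higher and 521 lower, removal of the length trend gave 1322 and 704, and limma-voom gave 1082 and 1507. Without uncontrolled culture 1, 2, 3 or 4 the count was 145, 150, 643 or 535, without negative feedback culture 1 or 2 it was 3204 or 2960, without paradoxical feedback culture 1, 3 or 6 it was 1099, 1003 or 1015, and without negative feedback cultures 3 to 7, which enter through the shared spread, it was 4818.

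**Figure D3:**
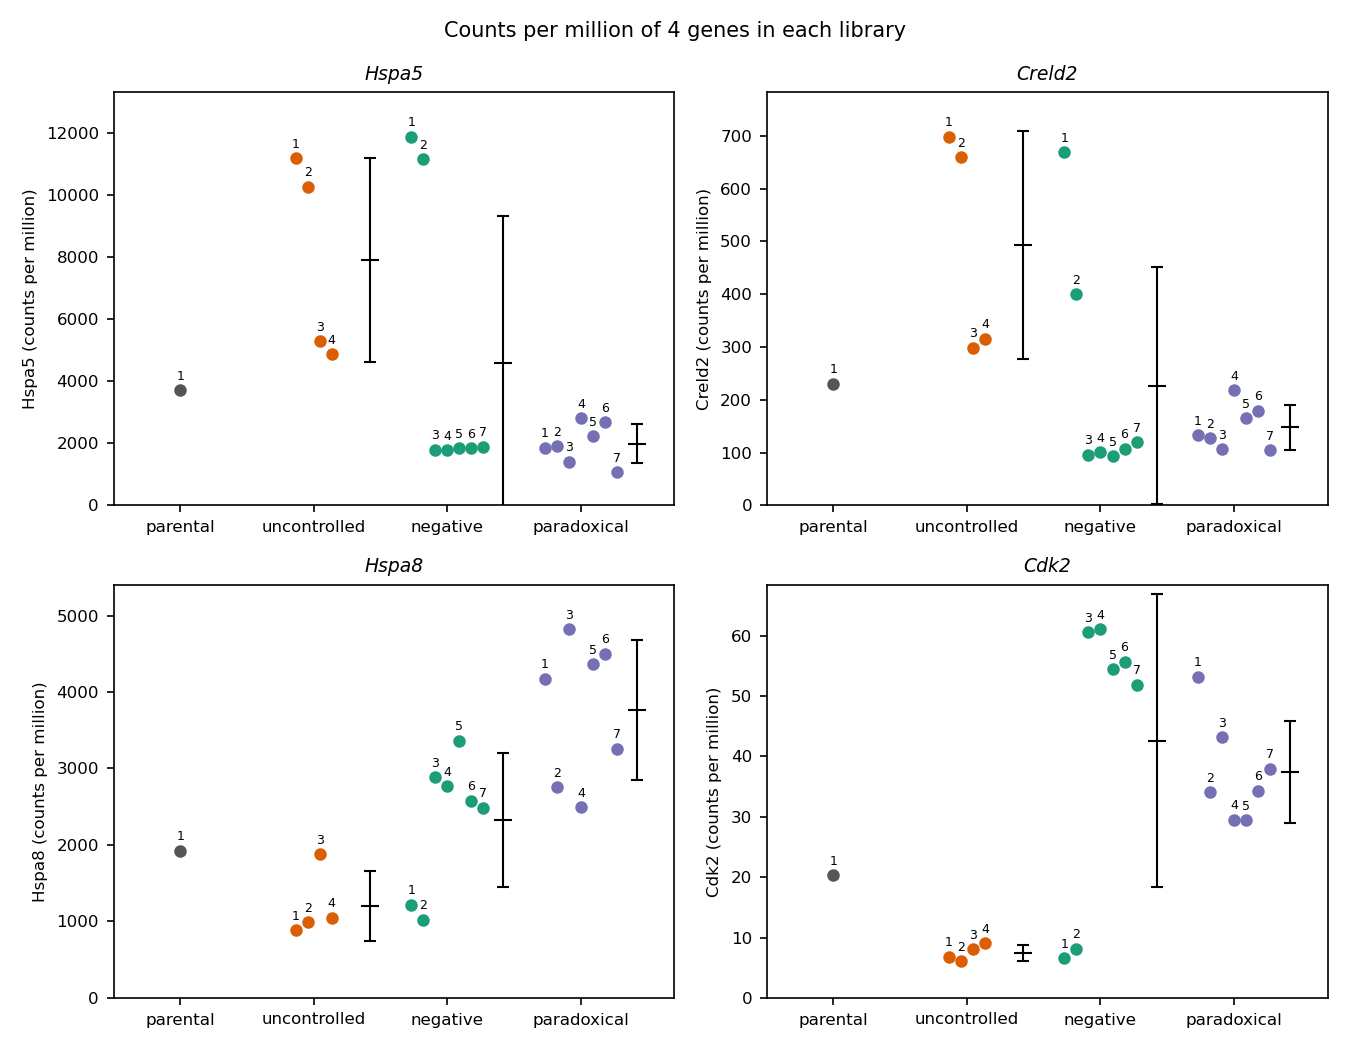
CPM of Hspa5, Creld2, Hspa8 and Cdk2 in each library by group, with points numbered by culture and bars showing mean and SD (the lower bar of Hspa5 under negative feedback is cut at 0). Negative feedback cultures 1 and 2 lie at 11872 and 11149 CPM for Hspa5 and cultures 3 to 7 at 1768 to 1896 CPM.

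In the direct comparison of paradoxical with negative feedback, edgeR called 1 named gene over all targets and 47 when adjusted over named genes alone, 24 higher and 23 lower. In the unfolded protein response list, members were lower under paradoxical feedback as a set (camera adjusted p = 0.00873, and 0.237 with an estimated correlation), with a median log2 fold change of -0.62 over 9 members. None of them was called singly. Edem1 was at -2.60 ± 0.62 (adjusted p = 0.0722), Hyou1 at -0.95 ± 0.23 with shared reads (0.0770), Hspa5 at -1.21 ± 0.49 (0.218) and Creld2 at -0.62 ± 0.45 (0.557), all by edgeR. These values mixed unlike negative feedback cultures. Edem1 was at 24.3 to 49.2 CPM in cultures 3 to 7 and at 1.79 and 1.65 CPM in cultures 1 and 2, and Hspa5 was at 11872 and 11149 CPM in cultures 1 and 2, whereas cultures 3 to 7 (1768 to 1896 CPM) lay within the paradoxical feedback range (1071 to 2802 CPM). Without cultures 3 to 7, Hspa5 at -2.52 (adjusted p = 0.00197) and Creld2 at -1.85 (0.00767) were called by edgeR, whereas Edem1 was at 1.45, Hyou1 at -0.041, Taldo1 at 0.033 and Rps13 at 0.12. NRF2 targets were higher as a set (camera adjusted p = 0.00837, and 0.178 with an estimated correlation), with a median of 0.47 over 4 members. Prdx1 was at 0.80 ± 0.21 (shared reads), Taldo1 at 0.49 ± 0.13 and Txnrd1 at 0.19 ± 0.18, with adjusted p from 0.0831 to 0.694 by edgeR. Ribosomal proteins were also higher as a set (camera adjusted p = 0.00837, and 0.360 with an estimated correlation), with a median of 0.38 over 9 members. Rps4x was at 0.55 ± 0.13 and Rps13, with shared reads, at 0.54 ± 0.15, with adjusted p of 0.0612 and 0.106 by edgeR. Adjusted over the list alone, 3 members of the unfolded protein response passed as lower, 3 NRF2 targets as higher and 2 ribosomal proteins as higher. The mean short-target share, 10.1 ± 1.38% under paradoxical (SD, n = 7) and 8.53 ± 3.54% under negative feedback (SD, n = 7), did not differ by exact permutation (p = 0.298, adjusted 0.448). Negative feedback cultures 3 to 7 (6.12 to 7.22%) nevertheless lay below every paradoxical feedback culture (8.50 to 12.4%), and cultures 1 and 2 (14.1 and 13.3%) above. A test of means cannot show this, so an influence of this share on the sets above is not excluded. The length index was lower under paradoxical feedback by 0.498, with an exact p of 0.0443 that did not pass after adjustment (0.109).

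Over all targets, edgeR called 77, 47 higher and 30 lower under paradoxical feedback, with 5033 at an unadjusted p under 0.05. The 1 named gene called was LOC100689009, chosen after its values were seen because it lies outside the rule, at 0.76 ± 0.12 (edgeR adjusted p = 0.0405, shared reads). Of the genes fixed by function, Ahr (-1.70 ± 0.54), Xiap (-2.61 ± 0.78), Abcb1 (-0.29 ± 0.13), Abcb1b (0.25 ± 1.30) and Casp9 (0.02 ± 0.39) did not pass, with adjusted p from 0.113 to 0.996 by edgeR. RLE scaling called 11, with 1 higher and 10 lower and a median log2 fold change over all targets of -0.12, removal of the length trend called 5 higher and 2 lower, DESeq2 called 1794 and limma-voom 297. Among named genes DESeq2 called 42, limma-voom 8, and edgeR called 23 with the length index as a covariate and 69 without negative feedback cultures 3 to 7. Leaving out uncontrolled culture 1, 2, 3 or 4 gave 2, 2, 47 or 0, negative feedback culture 1 to 7 in order 985, 863, 0, 0, 0, 0 or 7, and paradoxical feedback culture 1, 3, 4, 5, 6 or 7 gave 5, 0, 280, 0, 0 or 9. In the 8 of these fits without a call, 4143 to 4885 targets had an unadjusted p under 0.05. With negative feedback cultures 3 to 7 left out it was 2365.

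Comparison of the 18 long-term cultures with the parental library asked what changed over the time in culture, and no named gene passed. Among 284 named genes edgeR called 0, 4 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The genes fixed by function had log2 fold changes of 0.30 ± 0.27 for Abcb1, 0.45 ± 2.61 for Abcb1b, 0.90 ± 1.11 for Ahr, -0.58 ± 0.70 for Casp9 and 0.03 ± 1.57 for Xiap, each with an adjusted p of 1 by edgeR. No fixed list passed camera (0 of 11, smallest adjusted p = 0.790), 0 had an unadjusted p under 0.05 and fry called 0. Over all targets edgeR called 5 higher and 0 lower in the cultures, with 636 at an unadjusted p under 0.05. All 5 had shared reads and 0 or 1 count in the parental library, and the predicted transcript XM_016973291.2 had 1 count there and 315 to 1044 in the cultures. Without negative feedback culture 1, uncontrolled culture 1 or uncontrolled culture 2 the count was 11, 8 or 8, over whole targets it was 0 with 38 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 298 and 100. As a description, 41 targets lay at least 2-fold above the parental value in all 18 cultures and 60 at least 2-fold below it, none of them whole, against 38 to 197 and 35 to 210 when each culture in turn took the place of the parental library.

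Averaged over pairs, cultures under negative feedback lay farther from each other than those under paradoxical feedback. The mean pairwise difference over 28555 targets was 1.66 log2 units in uncontrolled, 2.12 under negative and 1.77 under paradoxical feedback. Mean squared distances to the group mean were 1.37 ± 0.0702 (SD, n = 4), 2.36 ± 0.956 (SD, n = 7) and 1.57 ± 0.130 (SD, n = 7). By exact two-sided permutation, paradoxical feedback differed from negative feedback by -0.78 (p = 0.00466, adjusted 0.0140 over 3 comparisons) and from uncontrolled growth by 0.20 (p = 0.0273, adjusted 0.0409), whereas negative feedback and uncontrolled growth gave 0.99 (p = 0.0818). Negative feedback cultures 1 and 2 had the largest distances, 3.91 and 3.56, against 1.55 to 1.93 in cultures 3 to 7. In log2 CPM, cultures 3 to 7 correlated with each other by 0.860 to 0.877 and cultures 1 and 2 by 0.870. Uncontrolled pairs had 0.862 to 0.877, and pairs across the 2 negative feedback sets 0.664 to 0.734. All 7 distances were taken to 1 mean, so this single split raised them together and the permutation does not show that each culture diverged. Paradoxical feedback no longer passed against negative feedback without negative feedback culture 1 (-0.47, exact p = 0.379) or 2 (-0.54, 0.315), nor against uncontrolled growth without uncontrolled culture 1, 2 or 3 or paradoxical feedback culture 2 (exact p = 0.0667, 0.05, 0.0750 and 0.0524). Negative feedback and uncontrolled growth passed without any 1 of negative feedback cultures 3 to 7 (exact p from 0.0190 to 0.0333). Over whole targets the first 2 differences were no longer past the threshold (p = 0.416 and 0.0879, exact).

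The mean changes under both feedback conditions against uncontrolled growth ran in the same direction across transcripts. Named genes called higher in both included Cdk2, Cdc25b, Parp1, Hsph1, Icam1 and Cdt1, and Slc20a1 was called lower in both. Under negative feedback these calls rested on cultures 3 to 7. Without them the genes called higher ran from -0.21 for Cdt1 to 0.35 for Icam1, Slc20a1 was at -0.32, and none was called. In all, 852 targets were called higher in both comparisons, 96 lower in both and 0 in opposite directions, where independent lists of these sizes would share 122 and 4.74. Both comparisons share the 4 uncontrolled cultures, so independence is not what unrelated changes would give. In 20 simulated fits without any effect and with the same shared controls, at most 1 target was called and the overlap was 0. With so few calls, these fits give no expected overlap for lists of the real sizes. The log2 differences correlated across targets with r = 0.757, which is not a test because genes are not independent replicates. Simulated unchanged groups gave a median r of 0.550 (95% of 1000 draws from -0.00466 to 0.860), and 132 draws were as high. The covariance was 1.51, against a mean of 0.352 in the simulation, where 0 draws were as high, a difference of 1.16. With the controls split into 2 pairs, r was 0.4996 (0.486 to 0.514) and the covariance 1.17. Without negative feedback cultures 3 to 7, r was 0.269. The relation was not adjusted for the share of counts on short targets.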

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

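Single cultures stood apart from the others of their group, by Dixon's ratio, in 8 of 213 comparisons over 27 library measures and 186 genes by group, all 8 of them genes. Chance marks about 1 in 20 such groups, so this number is no larger than chance gives, and no explanation was weighed.

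Hspa8 and Stip1, both heat shock chaperones, were highest in uncontrolled culture 3, at 1875 CPM against 885 to 1048 CPM in the other 3 uncontrolled cultures and at 406 CPM against 300 to 316 CPM. Top2a and Xiap, an inhibitor of caspases, were highest in uncontrolled culture 4, at 464 CPM against 270 to 301 CPM and at 2.54 CPM against 0.247 to 0.554 CPM. Paradoxical feedback culture 3 had the highest Casp8, at 42.6 CPM against 30.2 to 35.4 CPM in the other 6. Paradoxical feedback culture 1 had the highest Slc2a1, at 37.6 CPM against 23.9 to 27.9 CPM, and the highest Apex1, a base excision repair enzyme with shared reads, at 33.9 CPM against 23.0 to 27.5 CPM. Ldha, with shared reads, reached 4.40 CPM in negative feedback culture 4 against 0 to 1.65 CPM in the other 6.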

How the results depend on the processing

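Whole targets only, the length index as a covariate, removal of the length trend, omission of negative feedback cultures 3 to 7, the set test against named genes and edgeR's fitted folds in the relation were chosen after the data had been seen. Cultures 3 to 7 were picked because they lay apart in the measured values, so the fit without them shows only what rests on them. The other alternatives were fixed before the data were examined. The cause of the shifts below was not tested unless stated.

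Of 2787 targets called for negative feedback against uncontrolled growth, the count became 6436 with DESeq2, 5039 with limma-voom, 9 with only the groups compared, 4 with a replicate block, 5 with the length index and 13 without negative feedback cultures 3 to 7, which leaves 2 cultures in that group. Of 1835 for paradoxical feedback against uncontrolled growth, it became 4823, 4362 with only the groups compared, 3, 3545 and 4818 under DESeq2, that fit, the block, the index and the omission. Of 77 between the feedback conditions, it became 11 with RLE scaling, 42 with library size alone, 2 with no filter, 167 with the CPM filter, 1794 with DESeq2, 297 with limma-voom, 0 with only the groups compared (4610 at an unadjusted p under 0.05), 0 with the replicate block (3283 unadjusted), 315 over whole targets, 646 with the index, 7 with the length trend removed and 2365 with the omission. Of 5 against the parental line, it became 298 with DESeq2, 100 with limma-voom, 0 over whole targets (38 unadjusted), 12 with the index, 8 with the trend removed and 8 with the omission. Leaving out each culture gave 7 to 6931, 145 to 3204, 0 to 985 and 5 to 11 calls in that order of comparisons. All other alternatives stayed within 1.5 times the count.

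The replicate numbers do not pair the cultures: same-numbered cultures correlated by -0.156 to 0.107 in their deviations from the group means, and 1 of 15 pairs was above 0.1, so the block is reported only as a count. With it, all 67 calls of named genes were lost.

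The number of fixed lists passing was 0, 3, 3 and 0 in that order. With fry it was 2, 5, 2 and 0, with an estimated correlation 0 in every comparison, against named genes alone 1, 2, 3 and 0, and with the length index 0, 5, 6 and 0. Leaving out each culture gave 0 to 1, 2 to 5, 2 to 7 and 0 to 0.

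The spread of 1.66 in uncontrolled, 2.12 in negative and 1.77 in paradoxical feedback cultures became 1.70 and 1.83 with the CPM filter for the first and last, 2.74, 4.43 and 3.48 over the 1000 most variable targets, 2.26, 2.81 and 2.40 with a prior count of 0.5, and 0.627, 0.855 and 0.789 over whole targets. There the difference of paradoxical from uncontrolled cultures was 0.12 (exact p = 0.0879) and from negative feedback -0.13 (exact p = 0.416). Leaving out each culture gave 1.63 to 1.68, 1.98 to 2.19 and 1.75 to 1.79 for the groups, and 0.68 to 1.15, 0.16 to 0.25 and -0.94 to -0.47 for negative minus uncontrolled, paradoxical minus uncontrolled and paradoxical minus negative. The correlation of 0.757 became 0.4996 with split controls, 0.776 as Spearman's rho, 0.868 over whole targets, 0.269 without negative feedback cultures 3 to 7 and 0.721 with fitted folds, and 0.732 to 0.782 on leaving out each culture.

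Of 2967 alternatives over the results of named genes, 67 of which were called, 2285 stayed on the same side of the threshold, 619 lost the call, 50 gained it and 13 turned direction in called results. In 63 of the 2285, over 13 results not called in either fit, the sign also turned, among them Edem1 between the feedback conditions, Ahr, Xiap and Abcb1b. Of these 63, 44 were under alternatives fixed before the data were examined. Without an uncontrolled culture, 224 of 268 calls were lost. The 13 reversals of called results arose for negative feedback against uncontrolled growth without negative feedback cultures 3 to 7, where Dicer1 was at -1.49, Smu1 at -0.70, Gnaq at -0.50, Ccnd1 at -0.16, Cdt1 at -0.21, Top2a at -0.051, Casp2 at -0.51, Edem1 at -0.20, Slc2a1 at -0.058, Srebf2 at -0.14, Acaca at -0.015, Cdk2 at -0.019 and Gna11 at -0.021. At 9.91 to 13.2 M counts, depth limits targets at 0 to a bound of 3 counts, or 0.254 CPM. In the simulation 12% of 2-fold and 36% of 4-fold changes were recovered at the fitted spread, and 40% and 84% at 0.1 of it, so spread limits the test, and depth was not varied. The rescaling by length was not run, because the effective lengths are the same in all libraries and it would return the same values, and summing to genes could not be done because most targets matched no symbol.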

Other observations

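Gene groups assembled from the matched names, after the files had been seen and before any comparison was made, were tested beside the fixed lists. In this part, the tests of groups, other splits and explanations were chosen after the data or the result they bear on had been seen. The edgeR tests of single genes were planned. Member counts below are to be read against all 284 named genes, of which edgeR called 80 higher under negative and 56 under paradoxical feedback. With an estimated correlation, camera passed 0 of the 16 groups in any comparison. Microtubule and actin genes rose under paradoxical feedback against uncontrolled growth, with 6 of 9 called higher (camera adjusted p = 8.73e-06, and 0.184 with an estimated correlation). Tuba1b, an alpha-tubulin, rose by 1.57 ± 0.31 and Tuba1c by 2.10 ± 0.42 (edgeR adjusted p = 0.0142 for both), each with shared reads as is usual in this family. Genes of mitosis and cyclin-dependent kinases rose as a set under paradoxical feedback (camera adjusted p = 9.73e-06, and 0.184 with an estimated correlation), with 4 of 12 called, and under negative feedback (0.000324, and 0.385 with an estimated correlation), with 7 of 12 called. Nucleotide and folate metabolism had 5 of 12 members called higher under each feedback condition (camera adjusted p = 0.000717 under paradoxical and 0.00438 under negative feedback, and 0.247 and 0.385 with an estimated correlation). Adk rose by 0.98 ± 0.20 under paradoxical and by 1.01 ± 0.20 under negative feedback, and Adss2, an enzyme of AMP synthesis, by 1.92 ± 0.43 under negative feedback. DNA repair genes had 4 of 12 called higher under each feedback condition (camera adjusted p = 0.000703 under paradoxical and 0.0157 under negative feedback, and 0.184 and 0.385 with an estimated correlation), among them Apex1 (2.39 ± 0.45) under paradoxical and Ercc4 (2.98 ± 0.67) under negative feedback. Under negative feedback the rises of Adss2, Ercc4 and Adk rested on cultures 3 to 7, without which edgeR gave 0.062, 0.32 and 0.33 and no call.

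Under negative feedback, 5 more of the 16 groups passed camera against uncontrolled growth. These were sterol control (5 of 11 called, adjusted p = 0.0141), heterotrimeric G proteins (4 of 9, 0.0157), microtubule and actin genes (3 of 9, 0.0157), N-glycosylation and glycosyltransferases (8 of 28, 0.0210) and caspases with Bcl-2 proteins (3 of 9, 0.0466), all with an adjusted p of 0.385 with an estimated correlation. Pea15, which binds death effector proteins, rose by 1.27 ± 0.28 and Gna11, with shared reads, by 3.13 ± 0.66, but without negative feedback cultures 3 to 7 they were at 0.10 and -0.021 and not called. Whether these groups differ between the feedback conditions was tested directly. In that comparison camera passed the microtubule and actin group (adjusted p = 0.00602) and the ribosome and elongation group (0.00153), both higher under paradoxical feedback and both at 0.466 with an estimated correlation. Against other named genes alone the ribosome and elongation group passed (0.0229, and 0.602 with an estimated correlation) and the microtubule and actin group did not (0.0651). The other groups did not pass. Named genes as a whole had a median log2 fold change of 0.44 under negative and 0.55 under paradoxical feedback against 0.03 and 0.02 for other targets. Set against other named genes alone, none of the 8 groups that passed as higher under negative feedback passed, and ribosome and elongation genes passed as lower (adjusted p = 0.0145). Under paradoxical feedback the microtubule and actin group passed as higher and folding in the endoplasmic reticulum as lower (0.0223 for both). With an estimated correlation 0 of the 16 groups passed in this form, at 0.706, 0.889 and 0.874.

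Negative feedback cultures 3 to 7 lay apart from cultures 1 and 2, and the labels give no subgroup, so no biological explanation was tested. The separation was not made by dividing reads among similar transcripts, because over whole targets the gap on the first principal component was 6.75 times the range within cultures 3 to 7. A smooth trend with transcript length did not account for it either, since with that trend removed the gap was 7.46 times the range. An exchange of labels between negative feedback and uncontrolled cultures would place some uncontrolled cultures among cultures 3 to 7, and 0 did. Uneven read coverage along transcripts stays open and may contribute, because named targets whose length is a multiple of 3, as in records of coding sequence without untranslated ends, stood higher relative to other named targets in each of cultures 3 to 7 than in 1 and 2, by at least 0.393 log2 units with the trend removed. Length alone does not mark such records, since 37.9% of predicted coding transcripts also had a multiple of 3.

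Against uncontrolled growth edgeR called named genes almost only higher, 80 to 1 under negative and 56 to 3 under paradoxical feedback, but the balance depended on the method, with 44 to 24 and 43 to 9 by limma-voom, 68 to 8 and 45 to 9 over whole targets, and 120 to 14 and 89 to 8 when adjusted over named genes alone. With the length index as a covariate or without cultures 3 to 7, edgeR called 0 named genes under negative feedback, with 12 and 1 at an unadjusted p under 0.05. Under paradoxical feedback 85 of 97 named calls were higher with the index as a covariate, 87.6%, but this does not exclude uneven coverage, because no difference in the index passed between these groups (0.195, exact p = 0.155), while one in the median of coding-length named targets did (0.63, adjusted p = 0.0364), and genes are not independent. This test replaced an earlier form, in which the difference of medians between coding-length and other named targets was 0.263 ± 0.0963 with the covariate against 0.332 ± 0.134 without it (bootstrap SD) and lay too near its bound to decide. Under negative feedback the same difference was 0.117 with the covariate against 0.569 without, but the index separates cultures 3 to 7 from all other libraries, so coverage and condition cannot be told apart there. Uneven coverage stays open for both, as does a difference of the culture conditions themselves.

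Hspa5 was lower under paradoxical feedback than in uncontrolled cultures, at -1.99 ± 0.56. A smooth length trend is argued against as its whole cause, since the log2 fold change was -2.09 ± 0.57 with the trend removed. It was -1.59 ± 0.29 with the index as a covariate, which does not decide, because no difference in the index passed between these groups, and both were past the threshold in edgeR (adjusted p = 0.0393 and 0.00276, within a range of 0.000869 to 0.219 over its alternatives). A reduced unfolded protein response as a whole is a candidate explanation that the data did not settle, because the 8 other tested members of the list had a median of -0.105 with an SD of 0.84 (-0.21 without Canx, which had 0 counts in both groups) and ran from -1.74 for Creld2 to 1.25 for Edem1. Hspa5 and Creld2 also separated within negative feedback, at 11872 and 11149 CPM for Hspa5 in cultures 1 and 2 against 1768 to 1896 CPM in cultures 3 to 7, and the uncontrolled cultures varied from 4868 to 11184 CPM.

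Other splits of the same libraries tested whether chance gives as many calls. For paradoxical feedback against uncontrolled growth, 1 of 100 splits, the real one, reached its 1835 calls, and the highest other split gave 816. The 100 were taken from 330 possible splits. With 0 of 99 other splits (exact 95% interval 0 to 3.66%), this argues against chance but does not exclude it. For negative feedback against uncontrolled growth, 4 of 100 splits, the real one included, reached 2787 calls, and for paradoxical against negative feedback 4 of 100 reached 77. Both shares are under 0.05, but 3 of 99 other splits leaves an exact 95% interval of 0.629 to 8.60%, so chance is not firmly excluded for either. In both cases other splits gave more calls than the real one, up to 7543 when negative feedback cultures 3, 4, 6 and 7 were set against the rest and up to 3854 when negative feedback cultures 1 and 2 were parted from 3 to 7. These larger counts point to the structure within the negative feedback group.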
